A study of Homo sapiens with 19 samples.

How the data were processed

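Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map the retinoblastoma protein RB in C4-2 and VCaP cells, and V5-tagged E2F1 in C4-2 cells. Both are established prostate cancer cell lines. Per the labels, the 19 libraries fall into 10 groups. RB was mapped in untreated C4-2 cells (2 libraries) and untreated VCaP cells (1 library). V5 was mapped in C4-2 lines that carry a tetracycline-controlled E2F1, either wild type (WT) or the K185R mutant, with 2 libraries for each of 4 treatments: untreated, doxycycline (0.25 ug/ml for 3 days), GSK2879552 (50 uM for 24 hours), and doxycycline followed by GSK2879552. GSK2879552 is an inhibitor of the lysine demethylase LSD1. Libraries were made with the SMARTer ThruPLEX kit, per the labels' protocols.

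The submitters' processing notes name FastQC 0.11.9, BWA 0.7.9a, SAMtools 1.2 and MACS2 2.1.0, and the build hg19. The role and settings of each tool, the removal of duplicate reads and the use of a control library are not given in the sources used here. The authors deposited 1 list of MACS2 intervals per group, 10 lists in all. Each list stands for a whole group, so the spread between its libraries cannot be measured. The interval names of the V5 lists say that libraries were merged, while those of the C4-2 RB list carry the name of a single library, so the joining of its 2 libraries is not stated. The labels put each list in its group. The names of the V5 lists carry the words siNTC and siRB where the treatment labels say untreated and doxycycline. The groups follow the treatment labels, and the sources used here do not settle which is right. They also do not say whether tagged E2F1 was present without doxycycline.

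Each deposited interval comes with the authors' fold enrichment (a linear ratio of reads at the summit to the local background), their p-value and q-value on the −log10 scale, and the position of the summit. These are values of single intervals and were used only to describe, rank or filter intervals within a list. The deposited fold and −log10 p together fix 2 further quantities. MACS2 adds 1 read to both terms of the fold and takes p from a Poisson distribution, so the number of reads at the summit and the expected local background could be solved for each interval. Recomputed −log10 p differed from the deposited value by at most 0.00016 in any list. In simulated intervals, 1000 for each list, at least 99.9% of the summit reads were recovered. The lowest background shared by at least 5 intervals of a list, here called the floor, is the genome-wide expectation, and 2 intervals of the C4-2 RB list lay under it. The floor divided by the fragment length (the smallest interval width) gives the depth in reads per kilobase of the effective genome. Backgrounds above the floor were whole reads per 10 kilobases, within 0.05 reads, for 100% of intervals in each list, where 10% would come out whole by chance. They also held at least the reads of the summit itself, as happens when the background is estimated from the ChIP library.

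Lists were compared by their length and by overlap. An interval counted as shared when it overlapped an interval of the other list by at least 1 base. Shares are given for the shorter list of a pair with 95% Wilson intervals. These cover counting error over intervals only, since intervals are not replicates and the spread between libraries cannot be measured. Reads from PCR without molecular identifiers are also not independent molecules. Chance overlap was the mean over 100 seeded rotations of a list along its chromosomes. Rotation does not keep the regions where intervals tend to lie, so it sets a low bar. A difference between 2 lists has no replicate check, and no p-value was computed for it. The 8 V5 lists also form a full cross of protein, doxycycline and GSK2879552. For each factor, 4 lists were set against the other 4 with a two-sided exact permutation test over 70 splits, which cannot give a p below 0.0286. Benjamini-Hochberg adjustment was made over 9 such tests (3 measures by 3 factors), and other uses of this test were not adjusted. This test was chosen after the data had been seen. Its unit is the list, and the 4 lists on one side differ in treatment, so they are not replicates. Lists were also matched on the other factors and the signs of the 4 differences flipped, an exact test that cannot give a p below 0.125.

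Alternatives fixed before the data were examined were a stricter threshold (−log10 q of at least 5), covered bases in place of interval number, an overlap of at least 50% of both intervals, summits within 100 bases, and the 1000 intervals of highest −log10 q in each list. Others were added after seeing the data. One left out intervals whose local background was at least 10 times the floor of their list, called high background here, from both lists compared. Another left out only RB sites of high background and kept all V5 intervals. It was added last, after the results of the others were known, and is used where the report and the closing part count low-background RB sites with a V5 interval. A further one thinned the reads of each V5 list to the depth of the shallowest list and kept the expected number of intervals that still passed one −log10 p cutoff of 4.30. It starts from deposited intervals, so intervals that would be called only at a lower depth are missing, which can undercount the deeper lists. Others kept only intervals wider than 1 fragment, used RB sites of VCaP, of both lines or of C4-2 alone, combined the top 1000 intervals with low background, or left out each list in turn. The cut on local background follows the depth of a list, and the background holds the interval's own reads, so strong V5 intervals can be left out too. On chromosome 3 at 196625598 to 196625816, the C4-2 RB background was 3.01 reads, 3.67 times the floor. The untreated WT V5 interval there had 3.59 reads, 18.4 times its floor.

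Regions are named by their hg19 coordinates, counted from 1. The rule was fixed before the data were examined. For each comparison it takes the 3 intervals of highest −log10 q found only in the longer list, the 3 found only in the shorter list, and the 3 of the shorter list that both share. Gene annotation, promoter shares, the 12 gene lists written beforehand and the E2F sequence motif were not analysed here, because no hg19 genome or annotation was used. Signal tracks were not used here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.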

Results

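RB and V5-tagged E2F1 were mapped by ChIP-seq in prostate cancer cells grown in charcoal-stripped serum. RB is the pocket protein that binds E2F transcription factors, and E2F1 is the best-studied of them. The series asks how RB, E2F1 and the demethylase LSD1 relate in castration-resistant prostate cancer. K185R replaces a lysine of E2F1 by arginine. Each of the 10 groups is represented by 1 list of intervals, so values below carry no replicate error. The names of the V5 lists say siNTC and siRB where the labels say untreated and doxycycline. Every statement on doxycycline therefore holds for the groups as labelled.

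The lists differed widely in length and depth. RB gave 9146 intervals in C4-2 at a depth of 8.21 reads per kilobase and 17026 in VCaP at 2.98. The V5 lists were shallower, from 0.72 reads per kilobase in WT with GSK2879552 to 1.79 in untreated K185R. WT V5 lists held 15099 intervals untreated, 64025 with doxycycline, 2805 with GSK2879552 and 3874 with both. K185R lists held 55681, 22328, 9899 and 3498 in the same order. The median summit rested on 14 reads in the C4-2 RB list and 12 in the VCaP list, but on 5 or 6 reads in the V5 lists. Between 47.3% and 74.7% of V5 intervals had 5 or fewer reads at the summit. Between 49.95% and 64.2% of V5 intervals had the smallest width of their list, against 9.96% and 16.3% in the RB lists. RB intervals were denser on gene-rich chromosome 19 than on gene-poor chromosome 18, with 2.87 intervals on 19 for each on 18 in C4-2 and 3.37 in VCaP. The same ratio was 0.95 or less in 7 of the 8 V5 lists, and in WT with GSK2879552 it rested on 66 intervals on 19 and 65 on 18.

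RB sites of C4-2 and VCaP overlapped far more often than after rotation. Of the C4-2 RB intervals, 5420 of 9146 (59.3%, Wilson interval 58.3 to 60.3) overlapped an RB interval of VCaP, against 0.362% after rotation. This is 163.9 times the rotated share, and compared pairs of V5 lists also exceeded theirs, by 27.2 to 244.8 times. By summits within 100 bases the share was 38.6%, and among the 1000 strongest intervals of each list 37.7%. In the other direction the share was 30.2% of the longer VCaP list. Strongly bound VCaP sites were shared most often: 62.2% of the 4257 sites with the highest −log10 q lay in the C4-2 list, against 9.92% of the 4256 sites with the lowest. In C4-2, 64.3% of the 2287 highest and 51.5% of the 2286 lowest were in the VCaP list. Shared C4-2 sites had a median fold enrichment of 5.91 and those absent from VCaP 5.43.

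Named RB regions differed in how many other lists held them. The strongest shared interval lay on chromosome 3 at 196625598 to 196625816, with a fold enrichment of 37.4 and 149 summit reads in C4-2, and all 10 lists had an interval there. The VCaP interval on chromosome 20 at 734465 to 734865, with a fold of 19.1 and 69 reads, occurred in no other list. The VCaP interval on chromosome 21 at 47604332 to 47604688, with a fold of 16.2 and 63 reads, was also in VCaP alone. The 3 strongest C4-2 intervals without a VCaP counterpart lay on chromosome 9 at 70076661 to 70076843, on chromosome 6 at 119558521 to 119558723 and on chromosome 9 at 70327401 to 70327582. Their folds were 29.96, 29.9 and 30.8, and each was present in 9 lists, which are all but VCaP. The VCaP list was 1.86 times as long as the C4-2 list and covered 3.34 times as many bases. With at least 50% of both intervals required, the shared part of the C4-2 list was 22.8%, where the fragment lengths were 100 bases in C4-2 and 213 in VCaP.

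In the full lists, V5 intervals lay at more RB sites in WT than in K185R lists under each of the 4 treatments. The sources do not say whether tagged E2F1 was present without doxycycline, so a V5 interval in those lists is given as an interval and not as E2F1. V5 intervals overlapped 14.1% of the C4-2 RB sites in untreated WT cells (Wilson interval 13.4 to 14.8) and 11.4% in untreated K185R cells (10.7 to 12.0). With doxycycline the shares were 11.8% and 8.53%, with GSK2879552 12.5% and 8.998%, and with both 13.9% and 6.07%. Rotated RB sites met these lists in at most 0.846% of cases on average. The mean over 4 lists was 13.1% ± 1.08 (SD) for WT and 8.74% ± 2.17 for K185R, a difference of 4.35 percentage points (exact permutation p = 0.0286, n = 4 lists against 4). That is the smallest p this design can give, and after adjustment over 9 tests it was 0.0857, which does not pass 0.05. With lists matched by treatment, WT was higher in 4 of 4 pairs (exact sign-flip permutation p = 0.125, the smallest that 4 pairs can give). Shares of VCaP RB sites were lower, 3.90% ± 0.961 for WT and 1.59% ± 0.457 for K185R, and differed in the same direction (exact permutation p = 0.0286, n = 4 lists against 4).

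RB sites of low background that both cell lines share were set against all V5 intervals, those of high background included. Among 5212 such sites, WT lists had a V5 interval at 8.56% untreated, 4.70% with doxycycline, 10.1% with GSK2879552 and 11.5% with both. K185R lists had one at 3.32%, 2.02%, 3.36% and 1.46%. The means were 8.71% and 2.54%, a 3.43-fold ratio (exact permutation p = 0.0286, n = 4 lists against 4). Without V5 intervals of high background they were 7.99% and 1.775% (exact permutation p = 0.0286, n = 4 lists against 4). At the 3497 low-background RB sites found in C4-2 alone, WT lists covered 16.7%, 16.0%, 12.6% and 13.3% and K185R lists 16.3%, 12.2%, 11.95% and 8.06% in the same order. The means there were 14.7% and 12.1% (exact permutation p = 0.171, n = 4 lists against 4), and the difference between these classes of RB sites was not tested. Between the WT and K185R lists without treatment, 463 of the 8709 low-background RB sites of C4-2 had a V5 interval in WT alone, 177 in K185R alone and 567 in both. With doxycycline plus GSK2879552 these numbers were 765, 60 and 298. With only the 1000 strongest V5 intervals of each list, the difference in share of C4-2 RB sites was 1.41 percentage points (exact permutation p = 0.0857, n = 4 lists against 4). For the share of all C4-2 RB sites in the full lists, leaving out any 1 of the 4 WT lists gave an exact permutation p of 0.0571.

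**Figure D1:**
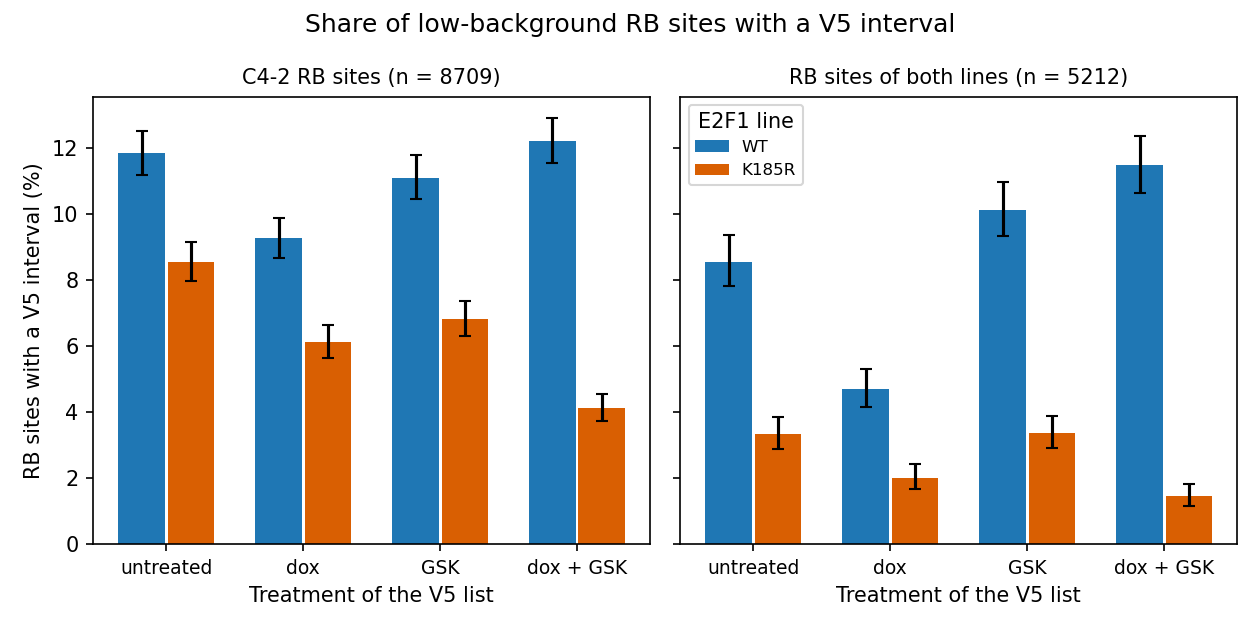
Percentage of RB sites (vertical axis) that overlap a V5 interval, by treatment (horizontal axis), for WT lists in blue and K185R lists in orange, at 8709 low-background C4-2 RB sites on the left and 5212 sites of both lines on the right. Bars are single lists and error bars are 95% Wilson intervals for counting error. Each WT bar lies above its K185R counterpart, with 12.2% against 4.11% on the left and 11.5% against 1.46% on the right for the combined treatment. V5 intervals of high background are counted. Without them the combined treatment gives 9.955% against 2.08% on the left and 10.8% against 0.729% on the right.

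Over whole lists, RB sites included, K185R lists were longer than WT lists under some treatments and shorter under others. The K185R list was 3.69 times as long as the WT list in untreated cells and 3.53 times as long with GSK2879552. It was 0.349 times as long with doxycycline and 0.903 times as long with both. Thinned to one depth, the ratio in untreated cells was 1.93 and that with GSK2879552 2.67. With GSK2879552 the direction turned at −log10 q of at least 5, where the ratio was 0.943. In untreated cells the stricter ratio was 2.41, and with both treatments 0.527. Shared intervals made up 23.2% of the shorter list in untreated cells, 23.1% with doxycycline, 26.5% with GSK2879552 and 17.4% with both, against at most 0.849% after rotation. These shares depended on the threshold: at −log10 q of at least 5 they were 59.2%, 55.7%, 48.3% and 74.0%, so the combined treatment turned from lowest to highest. At low background its share was 8.65%. Regions seen in WT but not in K185R included chromosome 14 at 53196732 to 53196953 and chromosome 6 at 33359418 to 33359653 in untreated cells, each with a fold of 12.4 and 20 reads. In cells with both treatments they included chromosome 4 at 83933991 to 83934253, with a fold of 14.8 and 24 reads. Each of these 3 regions had an interval in 7 or 8 of the 10 lists and overlapped an RB site of C4-2. Regions seen in K185R but not in WT untreated cells included chromosome 7 at 2852141 to 2852430, with a fold of 11.99 and 17 reads, where 4 lists had an interval.

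GSK2879552 lists were shorter in each of the 4 pairs. The WT list with GSK2879552 was 0.186 times as long as the untreated one, and 0.0605 times as long on top of doxycycline. In K185R these ratios were 0.178 and 0.157. Thinned to one depth, they were 0.306 and 0.121 in WT and 0.424 and 0.219 in K185R. At −log10 q of at least 5 they were 0.647 and 0.261 in WT and 0.253 and 0.404 in K185R. The geometric mean length was 4404 intervals with GSK2879552 and 33110 without, a ratio of 0.133 (exact permutation p = 0.0286, n = 4 lists against 4). The adjusted p over 9 tests was 0.0857. With lists matched on protein and doxycycline, the exact sign-flip permutation p over 4 pairs was 0.125, the smallest possible. The GSK2879552 lists were also shallower, 0.847 against 1.38 reads per kilobase on average (exact permutation p = 0.0286, n = 4 lists against 4). At −log10 q of at least 5 the ratio of lengths was 0.363. Without the WT doxycycline list, or without the untreated K185R list, the exact permutation p was 0.0571.

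At RB sites the pairs went both ways, and the difference between WT and K185R in this respect was not tested. With GSK2879552 the share of C4-2 RB sites with a V5 interval was lower in both K185R pairs (8.998% against 11.4% untreated, and 6.07% against 8.53% on top of doxycycline). In WT it was 12.5% against 14.1% untreated, and 13.9% against 11.8% on top of doxycycline. The mean share of C4-2 RB sites with a V5 interval was 10.4% ± 3.53 with GSK2879552 and 11.5% ± 2.28 without (exact permutation p = 0.686, n = 4 lists against 4). The direction turned without RB and V5 intervals of high background (6.34% against 5.89%), in lists thinned to one depth (10.2% against 9.72%) and at VCaP RB sites (2.99% against 2.50%), so no direction is given. It did not turn at low-background RB sites with all V5 intervals (8.56% against 8.93%). In WT cells, 31.6% of low-background V5 intervals (776 of 2458) lay at a low-background C4-2 RB site with GSK2879552, against 5.23% (758 of 14498) untreated. With doxycycline these shares were 24.5% (846 of 3450) with GSK2879552 and 0.797% (505 of 63367) without. In K185R cells they were 3.76% (354 of 9417) against 0.828% (455 of 54980), and 5.60% (175 of 3123) against 1.27% (276 of 21762). The K185R counts were thus lower with GSK2879552, and the shares higher because the lists were shorter. Among low-background RB sites in WT, 475 had a V5 interval in the untreated list alone and 412 in the GSK2879552 list alone. On top of doxycycline, 310 had one in the WT list without GSK2879552 alone and 567 in the one with it. In K185R these numbers were 282 and 131 untreated, and 212 and 38 on top of doxycycline. Low-background V5 intervals at low-background RB sites had median summit reads of 7 to 12, against 5 elsewhere in each of the 8 lists.

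Of the WT GSK2879552 list, 35.7% was shared with the untreated list, and of the list with both treatments 35.4% was shared with the doxycycline list. In K185R the shares were 26.0% and 25.3%. Regions present with GSK2879552 and not in untreated WT cells included chromosome 7 at 122526580 to 122526908, with a fold of 10.7 and 14 reads, and chromosome 2 at 171627297 to 171627579, with a fold of 9.95 and 13 reads. Each had an interval in 4 of the 10 lists. On top of doxycycline, the WT list held an additional interval on chromosome 1 at 51434175 to 51434475, with a fold of 14.7 and 24 reads, and on chromosome 19 at 14016782 to 14017074, with a fold of 12.5 and 22 reads. Each of these regions had an interval in 5 of the 10 lists.

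**Figure D2:**
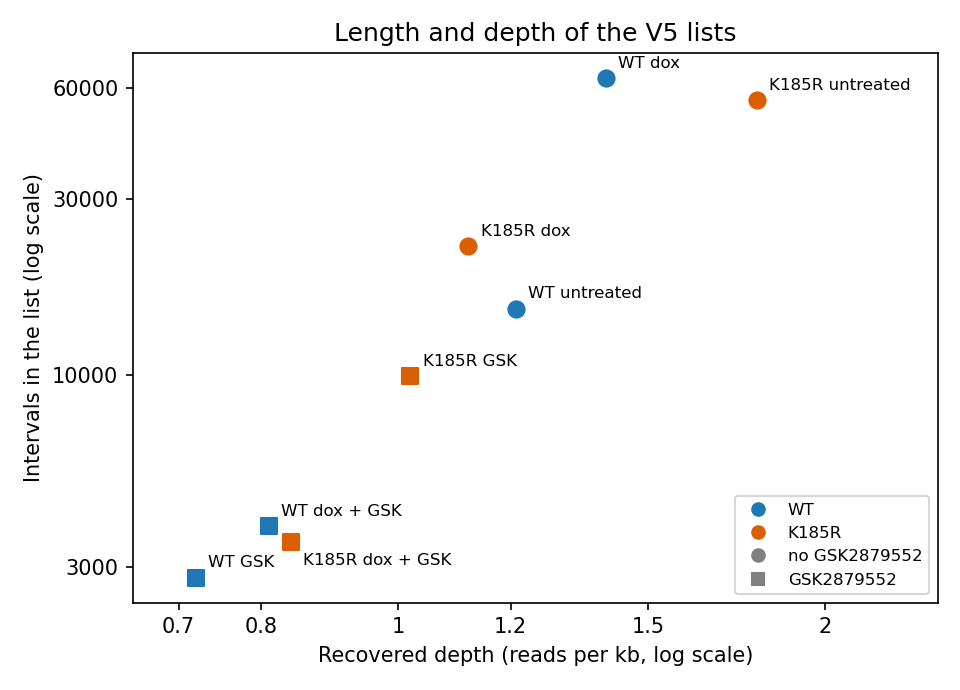
Number of intervals in each V5 list (vertical log axis) against the depth recovered from the list in reads per kilobase (horizontal log axis), 1 point per list, with WT in blue, K185R in orange, squares for GSK2879552 and circles for the rest. The 4 circles lie at 1.12 reads per kilobase or more and the 4 squares below that depth, with 9899 intervals at most.

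List length followed depth across the 8 V5 lists. Pearson's r on log scales was 0.95 (exact permutation p = 0.00042, n = 8) and Spearman's rho 0.93 (exact permutation p = 0.0022, n = 8). Without the 2 lists farthest from the median depth, untreated K185R and WT with GSK2879552, r was 0.96 (exact permutation p = 0.0056, n = 6) and rho 0.89 (exact permutation p = 0.033, n = 6). This was the one correlation computed. Depth does not overlap between lists with and without GSK2879552, and each side holds 4 lists, too few for a correlation of its own.

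Doxycycline, the usual inducer of tetracycline-controlled genes, went with a longer list in WT and a shorter one in K185R. The WT doxycycline list was 4.24 times as long as the untreated list, and 2.89 times at −log10 q of at least 5. The K185R doxycycline list was 0.401 times as long as the untreated one, but 0.847 times once both were thinned to one depth. Of the untreated WT list, 25.0% was found with doxycycline (Wilson interval 24.3 to 25.7), and of the K185R doxycycline list 20.4% was found in untreated cells (19.9 to 21.0), against 0.833% and 0.690% after rotation. Regions in the WT doxycycline list and not in the untreated one included chromosome 9 at 85274565 to 85274862, with a fold of 11.7 and 16 reads, and chromosome 12 at 24578901 to 24579112, with a fold of 11.6 and 15 reads. Each had an interval in 4 of the 10 lists. Regions in the untreated WT list and not in the WT doxycycline one included chromosome 14 at 96858042 to 96858368, with a fold of 11.7 and 19 reads. In all, 7 of the 10 lists had an interval there. In K185R, the doxycycline list held chromosome 6 at 11387521 to 11387753, with a fold of 9.61 and 12 reads, which was missing from the untreated list. Of the 10 lists, 3 had an interval at this region. Over the 4 lists on each side, the ratio of geometric mean lengths was 0.954. The share of C4-2 RB sites with a V5 interval was 10.1% with doxycycline and 11.7% without over the same lists (exact permutation p = 0.429, n = 4 lists against 4). In WT the longer doxycycline list met fewer of these sites than the untreated list, 1083 against 1288. With GSK2879552 the WT order was reversed, 1271 with doxycycline and 1145 without. In K185R doxycycline lists met fewer, 780 against 1039 and 555 against 823.

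Some of the strongest intervals of the V5 lists were common to all of them. Among the 1000 strongest intervals of each list, 45.9% to 66.4% were shared within a compared pair of V5 lists. An interval on chromosome 1 at 121483998 to 121485493 in untreated WT cells had 317 summit reads on a local background 177.4 times the floor, and all 10 lists had an interval there. The same held for chromosome 9 at 66970982 to 66971516, with a fold of 21.0, and chromosome 3 at 196625527 to 196625880, with a fold of 31.6. Of 85 intervals named by the fixed rule, 38 had a background of at least 10 times the floor. High-background intervals were fewer with GSK2879552 in each pair: 347 against 601 and 424 against 658 in WT, and 482 against 701 and 375 against 566 in K185R. They made up a larger share of the GSK2879552 lists, 9.73% against 2.20% on average, because the other intervals were fewer still.

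**Figure D3:**
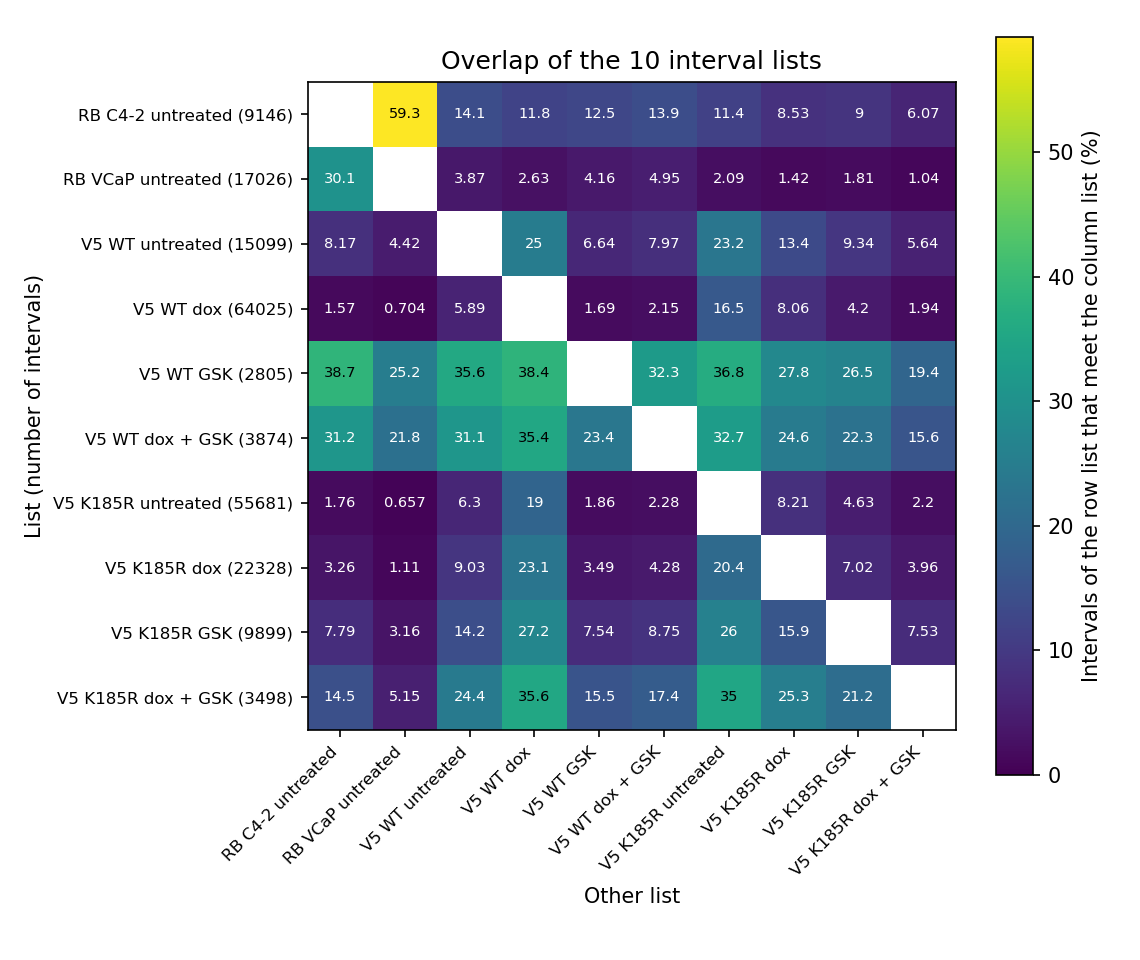
Percentage of the intervals of each list (rows, with the number of intervals) that overlap an interval of each other list (columns), from dark for low to bright for high. The RB lists of C4-2 and VCaP share most at 59.3% of the C4-2 list. The C4-2 RB list meets 38.7% of 2805 WT intervals with GSK2879552 and 1.57% of 64025 with doxycycline, which are 1086 and 1007 intervals.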

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

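All tests in this part were chosen after the data had been seen. Doxycycline went with more V5 intervals in both WT pairs and with fewer in both K185R pairs. The ratio of doxycycline to no doxycycline was 4.24 in WT without GSK2879552 and 1.38 with it, while in K185R it was 0.401 and 0.353. The opposite directions drew attention to these values, and the difference between the proteins was not tested, since an exact permutation of 2 pairs against 2 cannot give a p below 0.333.

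Depth went the same way, with the doxycycline list 1.15 and 1.13 times as deep in WT and 0.63 and 0.82 times as deep in K185R. After thinning to one depth the WT ratio without GSK2879552 was still 3.99 times the K185R ratio, which argues against depth as the whole cause. By parts, the thinned ratio was 3.38 for that WT pair and 0.438 for the K185R pair with GSK2879552, which depth alone would have brought near 1. It was 0.847 for the K185R pair without GSK2879552, which depth may account for. Thinning can undercount the deeper untreated list of that pair, which moves its ratio towards 1. It therefore cannot say how much depth accounts for there. The WT pair with GSK2879552 differed little, with a ratio of 1.33 when thinned and 1.17 at −log10 q of at least 5. At that threshold the K185R ratio was 0.652 with GSK2879552 and 0.409 without. An exchange of the untreated and doxycycline K185R lists alone would leave the pair with GSK2879552 in place, and that pair also had a low ratio of 0.353. An exchange in both K185R pairs would turn both ratios, and this check cannot exclude it. A biological difference between WT and K185R E2F1 stays open and untested, as does the meaning of the siRB names of the doxycycline lists.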

How the results depend on the processing

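The tests of 4 lists against 4, the filter on local background, the thinning, the filter on width, the matching of lists and the leaving out of lists were chosen after seeing the data. For the libraries, no paired analysis was possible because each deposited list stands for a whole group, so replicate numbers cannot be separated. Lists were instead matched on the other factors: the WT excess of 4.35 points and the GSK2879552 ratio of 0.133 held their direction in 4 of 4 pairs, each with an exact sign-flip permutation p of 0.125, the smallest that 4 pairs can give. Settings for promoter windows, the gene lists and the E2F motif, listed before the data were examined, were not run. Where a value below moved, the cause was not tested, except that thinning changes depth by construction. Shallow V5 lists limit what can be seen, since a summit of 5 reads can be lost with a few reads less.

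Ratios of list length kept their direction under covered bases and without high-background intervals in all 11 comparisons. At −log10 q of at least 5, K185R against WT with GSK2879552 turned from 3.53 to 0.943. At that threshold the GSK2879552 ratio was 0.647 in WT, and on top of doxycycline 0.261 in WT and 0.404 in K185R. K185R against WT was then 2.41 untreated and 0.527 with both treatments. VCaP against C4-2 was 3.34 in covered bases. Thinned to one depth, no ratio turned, but the K185R doxycycline ratio was 0.847, the GSK2879552 ratios 0.306 in WT and 0.424 in K185R, that in WT on top of doxycycline 0.121, and K185R against WT untreated 1.93.

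Shares of common intervals moved with each definition except that of RB in VCaP against C4-2 at low background and that of C4-2 RB sites in the untreated WT list at −log10 q of at least 5 (13.6%). They are given in the order doxycycline in WT and K185R, GSK2879552 in WT and K185R, GSK2879552 on top of doxycycline in WT and K185R, K185R against WT untreated, with doxycycline, with GSK2879552 and with both, and RB in VCaP against C4-2. With at least 50% of both intervals they were 19.7, 16.2, 31.4, 20.6, 29.9, 22.3, 18.3, 18.2, 23.7, 15.2 and 22.8%. With summits within 100 bases they were 20.6, 16.7, 31.1, 21.3, 29.3, 21.7, 19.4, 18.5, 23.0, 14.9 and 38.6%. At −log10 q of at least 5 they were 57.7, 57.9, 58.3, 76.3, 55.6, 83.1, 59.2, 55.7, 48.3, 74.0 and 53.0%. Among the 1000 strongest intervals they were 61.8, 66.4, 51.0, 61.5, 50.0, 51.4, 65.2, 61.2, 47.6, 45.9 and 37.7%. At low background the V5 shares were 22.3, 18.5, 26.9, 22.4, 27.7, 16.6, 20.4, 21.3, 16.8 and 8.65%. RB sites of C4-2 in the untreated WT list were 9.73% with at least 50% of both intervals, 11.8% by summits and 8.92% at low background.

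The WT excess at RB sites, as a mean over lists, stayed positive in all settings run. Single pairs were nearly level in some of them. At −log10 q of at least 5 the untreated shares of C4-2 RB sites were 13.63% in WT and 13.56% in K185R. With the 1000 strongest intervals the doxycycline shares were 6.593% and 6.517%, and with those of low background 2.319% and 2.205%. It no longer passed the exact permutation test of 4 lists against 4 with the 1000 strongest intervals (1.41 points, p = 0.0857), with those of low background (2.52 points, p = 0.0857), at −log10 q of at least 5 (2.32 points, p = 0.0857), with at least 50% of both intervals (2.66 points, p = 0.0571) and at low-background RB sites of C4-2 alone against all V5 intervals (2.52 points, p = 0.171). Leaving out each list in turn gave 3.46 to 5.22 points, and the exact permutation p was 0.0571 without any 1 of the WT lists. No adjustment was made over these settings, and in the main setting the adjusted exact permutation p was 0.0857. Unadjusted, the p of that test was 0.0286, its smallest, with VCaP RB sites, RB sites of both lines, summits, thinning, low background, and low-background RB sites against all V5 intervals. At RB sites of both lines the difference was 6.17 points in that last setting, a 3.43-fold ratio, and 6.21 points without high-background V5 intervals, a 4.50-fold ratio. For the GSK2879552 ratio of lengths the unadjusted exact permutation p was 0.0286 with thinning, −log10 q of at least 5, low background and wider intervals. Leaving out each list gave 0.102 to 0.166, and the exact permutation p was 0.0571 without the WT doxycycline list or the untreated K185R list.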

Other observations

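All tests in this part were chosen after the data had been seen. RB sites with a V5 interval recurred across treatments. Of 8709 low-background C4-2 RB sites, 342 had a V5 interval of any background in all 4 WT lists, where independent lists with the same shares would give 1.29. In all 4 K185R lists there were 297 such sites, where 0.127 would be expected. RB sites differ in strength, so lists are not independent even without tagged E2F1. Counting only low-background V5 intervals, 183 sites were in all WT lists (0.424 expected) and 116 in all K185R lists (0.0132 expected). Some of these sites still lay in a window of high background named below. Examples are chromosome 10 at 42418227 to 42418379 and at 42428665 to 42428834, both also in all K185R lists. With V5 intervals of any background, any WT list covered 1873 RB sites and any K185R list 917. WT lists alone covered 1078 and K185R lists alone 122. Of the 342 sites, 104 were also low-background RB sites in VCaP, 228 were in all K185R lists and 29 in none.

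Sites in all WT lists, in VCaP and in no K185R list are named here after their values were seen. The strongest RB interval among them lay on chromosome 1 at 155214462 to 155214927, with an RB fold of 21.1 and 99 summit reads. The next lay on chromosome 9 at 14322465 to 14322887, with a fold of 12.1 and 35 reads, and on chromosome 9 at 72873708 to 72874019, with a fold of 10.5 and 32 reads.

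V5 lists of WT cells held more RB sites than those of K185R cells. Thinned to one depth, the difference was 4.19 percentage points. K185R lists were on average the deeper, at 1.19 against 1.03 reads per kilobase, so thinning could hardly shrink the excess and does not itself decide on depth. The K185R list was deeper untreated (1.79 against 1.21), with GSK2879552 (1.02 against 0.72) and with both (0.84 against 0.81). It covered the smaller share each time, which argues against lower K185R depth as the cause in those pairs. With doxycycline the K185R list was the shallower, at 1.12 against 1.40, so depth stays open for that pair. Without high-background RB and V5 intervals the difference was 4.79. This argues against the intervals that the filter removes as the whole cause. The cut follows the depth of each list, so regions of high background are not removed alike from RB and V5 lists. List length may contribute: with the 1000 strongest intervals of each list the WT to K185R ratio was 1.22 instead of 1.497, a difference of 1.41 percentage points (7.91 ± 0.972 against 6.50 ± 0.635, exact permutation p = 0.0857 for 4 lists against 4). Among the 1000 strongest low-background intervals the p was also 0.0857 by the exact permutation test, but the ratio was 2.08, close to 2.29 over all low-background intervals, so the tables leave list length open. The WT doxycycline list, at 2.32%, lay within the K185R range of 1.75% to 2.71% there. A longer list does not by itself hold more RB sites, since in 2 of the 4 pairs the K185R list was the longer and covered the smaller share. With both treatments the lists were close in length, with 3498 K185R and 3874 WT intervals, and the shares were 6.07% and 13.9%. This argues against list length as the whole cause in that pair, which has no replicate check. A biological difference between the WT and K185R lines was not tested. The excess is also there without doxycycline, where the presence of tagged E2F1 is not known.

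V5 lists with GSK2879552 were 0.133 times as long as the others. Thinned to one depth the ratio was 0.242, and among intervals wider than 1 fragment it was 0.124, so neither depth alone nor stacks of reads 1 fragment wide account for all of it. At RB sites the share with a V5 interval was lower with GSK2879552 in both K185R pairs and in the WT pair without doxycycline. It was higher in the WT pair on doxycycline, so a part for RB sites is left open. Lower enrichment, library quality and an effect of LSD1 inhibition on E2F1 stay open, since each group has 1 list and the GSK2879552 lists are all shallower.

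In 5 windows of 1 Mb, the median local background was at least 10 times the floor in all 10 lists. They start at 42000001 on chromosome 10, 51000001 on chromosome 11, 46000001 on chromosome 16, 92000001 on chromosome 2 and 43000001 on chromosome 8.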
